A study of Mus musculus with 12 samples.

How the data were processed

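The series holds 12 one-colour Agilent arrays of RNA from abdominal-cavity macrophages of C57/BL6 mice, WT or GPR15 knockout, cultured in DMEM with 10% FBS and given PBS or LPS at 100 ng/ml for 4 h, with 3 arrays in each of 4 groups. Per the labels, total RNA was extracted with TRIzol and 0.1 µg was labelled with Cy3 by low-input amplification. The deposited files hold, per the file headers, signal intensity per spot, background and quality values in the output of Agilent Feature Extraction, version 11.5.1.1 in the submitters' processing notes. How the macrophages were separated from other cells, and whether replicates came from separate mice, is not given in the sources used here.

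Groups and replicate numbers were taken from the sample titles. Each array has 62976 spots, of which 3671 are controls and 59305 are not. The log2 of the processed signal was reduced by the 75th percentile of the array's non-control spots. Between 76 and 125 spots per array were marked as nonuniform or as population outliers. The spots of a probe were averaged without the marked ones, but a probe with all its spots marked on an array kept its value there. Of 56605 distinct probes, 32994 (58.3%) matched a transcript in a RefSeq gene table of assembly GRCm38.p6, which gave 22911 symbols. The files' own positions use an earlier assembly, so no positions are given and the table served only for names and for which genes lie next to each other. A probe was kept if it was well above background on all 3 arrays of at least 1 group. This left 28827 probes, 9761 of them without a symbol. Of the 7899 symbols with more than 1 probe on the array, and of all others, the probe with the highest mean over 12 arrays stood for the gene, which gave 13283 genes. The brightest probe may differ from the rest: of 4591 genes with several kept probes, 66 of 3497 with a call had probes called in opposite directions for LPS in WT, 127 of 3579 for LPS in KO, 2 of 808 and 89 of 2464 for KO against WT in PBS and after LPS, and 0 of 256 for the interaction.

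One linear model with a mean for each group was fitted over all 12 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation that lets the variance follow the mean level. Tests were two-sided, with Benjamini-Hochberg adjustment over the 13283 genes of each comparison and a threshold of 0.05. The comparisons were LPS against PBS in WT and in KO, KO against WT in PBS and after LPS, and the interaction, LPS minus PBS in KO less the same in WT. The average LPS effect over both genotypes served to choose the genes for the response size. The number of arrays limits the precision. Where a gene was not well above background on any array of one group, the fold was computed against the lowest signal well above background on those arrays and is a lower bound.

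The groups, comparisons, 22 gene lists, 12 cell-marker lists, the rule for naming genes and all alternatives not named below as added were set before the data were examined. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, adjusted over all lists of a comparison. Camera compares a list with the other genes, and fry asks whether its genes move on balance one way. Of list members, 11 of 19 alternative activation genes, 14 of 28 phagocytosis genes, 9 of 22 small peritoneal macrophage genes, 6 of 27 identity genes, 5 of 25 enzymes, 4 of 24 antigen presentation genes, 4 of 22 immediate early genes and 10 of 14 macrophage markers also stand in another list. The cytokine, interferon-stimulated, B-cell and T-cell lists share 0 members with others.

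Genes were named by a fixed rule. Gpr15 was always named. Among called genes well above background on all 6 arrays compared, with no overlap between the 3 arrays of each group, the 10 largest rises and 10 largest falls were eligible; for the interaction, genes well above background on all 12 arrays. Clone, predicted and locus names were passed over. The 5 largest lower bounds in each direction were added, and from each list up to 4 called members with the smallest p, or 2 if none was called.

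Replicate numbers were checked for pairing by correlating the residuals of equal numbers across groups. For LPS in WT these were 0.105, 0.371 and 0.481, and the equal number was the best match for replicates 2 and 3 only. They were 0.04, 0.113 and 0.081 for LPS in KO, where the equal number was the best match for each replicate. For KO against WT they were -0.042, -0.068 and -0.102 in PBS, and 0.017, -0.003 and -0.045 after LPS, with no such match. Pairing by number was therefore not settled in either genotype. No pair of arrays was a copy: the median difference was 0.0594 to 0.175 between replicates and 0.133 to 0.478 between groups.

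The steps were tested on simulated data with 200 changed genes among 13283 in 20 simulations. At 1.5-fold, 2-fold and 4-fold, 68.9%, 88.4% and 97.9% were recovered for LPS in WT, 69.7%, 88.1% and 98.1% for KO against WT after LPS, and 51.8%, 76.7% and 93.9% for the interaction. False calls made up 5.29%, 5.12% and 4.76% of calls. A simulated list of 30 moved genes was called in 20 of 20 simulations in each of these comparisons, and a list that did not move in 0. In the comparisons where nothing moved, that list was called in 2 of 20 simulations for LPS in KO and in 1 of 20 for KO against WT in PBS. The simulated noise was independent between genes and held no slide difference, and only 200 genes changed. These rates may therefore not hold for the real arrays.

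Most alternatives changed one choice at a time: quantile normalization, scaling to the median, normexp background correction with either scaling, no filter or a filter on all 12 arrays, the mean of a gene's probes or every probe by itself, moderation without trend or with robust fitting, array weights, only the 2 groups compared, the replicate number as a block, the slide as a block, at least 2-fold, an adjusted p below 0.01, and each array left out. The files give a median signal per spot in place of the mean signal planned for normexp, so the median signal with the local background and an offset of 50 was used. Both normexp fits thus changed the signal with the correction, and one of them the normalization too. Fits of slide 1 or slide 2 alone, of WT arrays alone with the replicate block, of autosomal genes and of the slide block with the filter on all arrays were chosen after seeing the data. Tables were read with data.table version 1.17.8 and jsonlite 2.0.0, and figures drawn with matplotlib 3.10.9. Probes without a symbol entered no list and no count of named genes; they entered the fit of every probe by itself and were counted apart. Slide 2 alone holds 1 PBS array, so its spread comes from the LPS arrays only and its counts were not used. With the slide as a block, LPS in KO and the interaction likewise take KO PBS from that array alone. In that fit KO against WT in PBS takes it from the KO PBS arrays of slide 1.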

Results

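Gene expression was measured on one-colour Agilent arrays in abdominal-cavity (peritoneal) macrophages from C57/BL6 mice that were wild type (WT) or lacked the G protein-coupled receptor GPR15 (KO). The cells received PBS or LPS, a bacterial cell-wall component that activates macrophages, at 100 ng/ml for 4 h. Each of the 4 groups held 3 arrays, 12 in all. Between 48.8% and 57.1% of the 59305 non-control spots of an array were well above background. The 75th percentile of the signal, which served to scale each array, lay between 469.6 and 574.1, and 0 spots were saturated. After filtering, 13283 named genes were tested. Replicate arrays of a group correlated across genes at 0.990 to 0.998, and genes are not independent replicates.

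The arrays lay on 2 slides, each with its own scan. Slide 1 held all WT arrays and KO PBS replicates 1 and 2, and slide 2 held KO PBS replicate 3 and all KO LPS arrays. LPS in WT cells was therefore compared within slide 1, whereas KO and WT cells after LPS never shared a slide. The first principal component carried 68.8% of the variance and parted LPS from PBS arrays. The second carried 15.7% and placed the slide 2 arrays, KO PBS replicate 3 included, at 24.5 to 29.3, against 6.6 and 8.0 for KO PBS replicates 1 and 2. The WT arrays, all on slide 1, lay at -29.4 to -9.1, so this component also parted the genotypes within slide 1. The labels give replicate numbers only, so the p-values may measure technical spread alone. Values after ± are standard errors of the limma fit on the log2 scale, with n = 3 arrays per group. For each gene named for the size of its change between a pair of groups, the 3 arrays of one group all lay beyond the 3 of the other. Random orders of 3 against 3 arrays give such a separation for 10% of genes.

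The first question was whether the arrays showed the loss of Gpr15 itself. Its single probe was well above background on 0 of 12 arrays. The signal lay between 6.02 and 15.2, whereas the lowest signal well above background on an array lay between 18.4 and 36.8. Gpr15 therefore gave no fold change, and the KO label could not be checked with it.

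Sex-linked genes, in contrast, parted the genotypes. Xist, the RNA that coats the inactive X chromosome, was well above background on 6 of 6 WT arrays and on 0 of 6 KO arrays. It was at least 10.9-fold lower in KO cells in PBS and at least 16.6-fold lower after LPS. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were all well above background on 6 of 6 KO arrays. Eif2s3y, which encodes a translation initiation factor subunit, was at least 54.5-fold higher in KO cells in PBS. Ddx3y, an RNA helicase gene, was at least 10.2-fold higher in PBS and at least 13.8-fold higher after LPS. Among WT arrays only LPS replicate 2 had a Y-linked gene well above background, Eif2s3y at -3.94 against 1.58 to 1.82 on KO arrays. The X-linked paralog Eif2s3x was higher in KO cells as well, by 1.82 ± 0.08 in PBS and 1.28 ± 0.08 after LPS. Its level in KO cells was 1.56 in PBS and 1.61 after LPS, near 1.70 and 1.72 for the Y-linked Eif2s3y. Whether its probe tells these paralogs apart was not tested. In the sex-linked list, 5 of 9 measured genes were higher and 4 lower in KO cells in PBS, with the same counts after LPS. The 5 higher ones in PBS were Eif2s3x and the Y-linked genes. The labels state no sex, and every comparison of KO with WT below is also a comparison of Y-positive with Xist-positive cells.

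**Figure D1:**
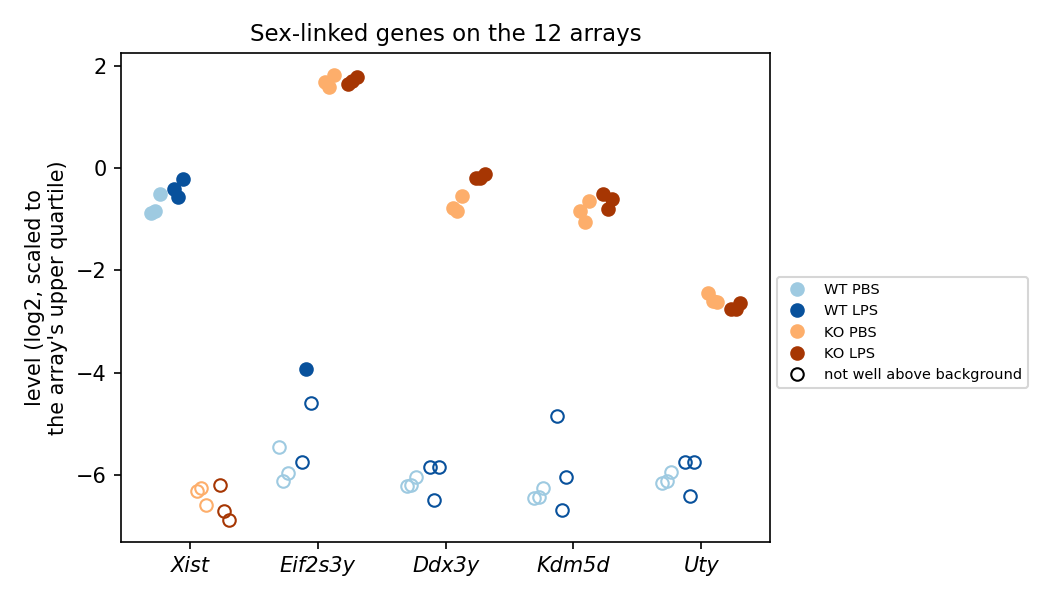
Log2 level, relative to the 75th percentile of each array, of Xist, Eif2s3y, Ddx3y, Kdm5d and Uty on each of the 12 arrays by group; open symbols stand for arrays on which the gene was not well above background. Xist was above background on 6 of 6 WT and 0 of 6 KO arrays, the Y-linked genes on all KO arrays, and Eif2s3y on 1 WT array at -3.94.

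Which genes LPS changed in WT macrophages was the next question. LPS raised inflammatory genes of these cells. Nos2, the inducible nitric oxide synthase, rose by 5.26 ± 0.38 on the log2 scale, or 38.2-fold. Cxcl10, an interferon-induced chemokine that attracts activated T cells, rose by 4.72 ± 0.13. The colony-stimulating factors Csf3 and Csf2, which drive the production of granulocytes and macrophages, rose by 4.68 ± 0.42 and 4.33 ± 0.19. Lcn2, which withholds bacterial iron carriers, rose by 4.35 ± 0.32, and the receptor gene Slamf1 by 4.60 ± 0.21.

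Further large rises in WT cells included Has1, a hyaluronan synthase, at 4.40 and Gfpt2, an enzyme of hexosamine synthesis, at 3.77. Mfsd2a, a lipid transporter gene, rose by 4.08 and Prok2, a secreted prokineticin, by 3.86 ± 0.48. Some genes were not well above background on any PBS array, so only a lower bound could be given. Il19, a cytokine of the interleukin-10 family, rose at least 78.1-fold. Cd70, a co-stimulatory ligand, rose at least 18.6-fold, the growth factor gene Gdnf at least 10.4-fold, Il3 at least 8.68-fold and Il22 at least 8.17-fold.

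Among the largest falls in WT cells, Clec4n, which encodes the fungal receptor Dectin-2, fell by 3.68, and its neighbour Clec4b1 fell by 3.75. Dcstamp, needed for the fusion of macrophages, fell by 3.49 and the motor gene Myo1f by 3.46. The kinase gene Srpk3 fell by 3.94, the amino acid transporter gene Slc43a2 by 3.33 and the small GTPase genes Diras2 and Rab7b by 3.32 and 3.28. Cacna1i, a calcium channel gene, fell by 3.30 and the T-cell chemokine gene Ccl17 by 3.25. Emid1 was at least 8.16-fold lower, Rab3a, a vesicle GTPase gene, at least 5.29-fold, and the lipid mediator transporter gene Spns2 at least 4.66-fold.

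Rises prevailed in several gene lists fixed beforehand, and 0 were called in WT cells with an estimated correlation. Of 20 measured pro-inflammatory cytokines, 15 rose, 1 fell and 4 were not called, with Ebi3 at 2.24 ± 0.06 and Il1a at 2.95 ± 0.11. The median change of that list was 1.92, or 1.79 with 3 genes held at their lower bound. All 33 measured interferon-stimulated genes rose, among them the exonuclease gene Isg20 at 2.92, the viral RNA sensor Ifih1 at 2.50 and the antiviral gene Oasl2 at 2.35. Their median change was 2.15. Negative feedback on NF-kB and TLR signalling rose in 22 of 26 genes and fell in 2; Tnfaip3, which removes ubiquitin from signalling proteins, rose by 2.25 ± 0.06, Tnip3 by 3.42 ± 0.09 and Il10 by 2.73 ± 0.10. Of 30 TLR4 and NF-kB signalling components, 18 rose, such as the adaptor gene Traf1 at 2.29 and Nfkb2 at 1.28, and 4 fell. The unfolded protein and heat shock list held 14 rises and 4 falls among 22 genes, with the stress genes Ddit4 at 1.72 and Chac1 at 1.31.

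Falls outnumbered rises in WT cells in other lists, of which 0 were called with an estimated correlation. Cholesterol biosynthesis fell in 12 of 21 genes and rose in 2, with the mevalonate pathway genes Mvk and Pmvk at -0.99 and -0.97. Cholesterol efflux and LXR targets fell in 11 of 18 genes and rose in 3; the fatty acid receptor gene Cd36 fell by 1.57 and Scd2, a desaturase gene, by 1.52. Antioxidant NRF2 targets fell in 11 of 20 genes, including Prdx6 at -1.33 and catalase (Cat) at -1.53, and rose in 3, including Sod2 at 1.04. Markers of B cells, which share the abdominal cavity with macrophages, fell in 10 of 13 genes and rose in 0, with Cd79b at -2.09 and Vpreb3 at -2.22.

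Across all genes, 8593 of 13283 (64.7%) were called at an adjusted p below 0.05 for LPS in WT cells, 4479 higher and 4114 lower, and 2071 changed at least 2-fold, 1002 higher and 1069 lower. With quantile normalization 3805 were higher and 4702 lower. With normexp background correction, which uses the median signal, 713 were at least 2-fold higher and 530 lower. Fitting slide 1 alone called 8714, of which 8355 were shared with the 12-array fit and went the same way. Residuals of WT replicates 2 and 3 correlated by number. A fit of the WT arrays alone with the replicate number as a block called 9356. Adjusted over the list alone, there were 23 rises in the feedback list, 11 falls among B-cell markers, 6 falls in the coagulation list, 7 rises and 19 falls in the cell cycle list and 2 rises among mast-cell markers, and the other counts were the same.

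The competitive list test called 9 lists for LPS in WT cells with a preset correlation between genes and 0 with an estimated one. Adjusted p was 1.1e-17 for interferon-stimulated genes, and adjusted p = 0.227 with an estimated correlation, the highest over 28 alternatives, whose lowest was 5.1e-28. For cytokines it was 6.1e-05, and adjusted p = 0.227 with an estimated correlation. The feedback list gave 1.2e-06, with adjusted p = 0.202 under an estimated correlation, and signalling components gave 0.0104, with adjusted p = 0.61 under it. Unfolded protein genes gave 0.015 and adjusted p = 0.444 with an estimated correlation. Among the falling lists, cholesterol biosynthesis gave 0.015 and adjusted p = 0.202 with an estimated correlation, and efflux genes gave 0.0239 and adjusted p = 0.227. NRF2 targets gave 0.0461, with adjusted p = 0.431 under an estimated correlation and 0.0612 on slide 1 alone. B-cell markers gave 7.4e-05 and adjusted p = 0.431 with an estimated correlation. Slide 1 alone gave the same list medians, since it holds every WT array.

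KO macrophages were then asked the same question. LPS raised inflammatory genes in KO cells too. Csf3 rose by 5.87 ± 0.42, Csf2 by 4.62 ± 0.19 and Has1 by 5.17 ± 0.22. Cxcl5, a neutrophil-attracting chemokine, rose by 4.73 ± 0.36, Cd70 by 5.14 ± 0.27 and Slamf1 by 4.58 ± 0.21. Cdk5r1, a kinase activator gene, rose by 4.02 ± 0.07. Il19 was at least 34.7-fold higher, the transporter gene Slco2b1 at least 31.9-fold and Cyp1b1, a steroid-oxidising enzyme gene, at least 17.0-fold.

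Falls in KO cells overlapped with those in WT cells. Cacna1i fell by 3.63, Diras2 by 3.62, Myo1f by 3.58 and Rab7b by 3.33. Clec4b1 fell by 3.33, Clec4n by 3.00 and Clec1b, a platelet and myeloid lectin gene, by 3.05. Susd3 fell by 3.12, Tmem163, a zinc transporter gene, by 3.06 and Tbc1d10c by 3.04. The chemokine scavenger gene Ackr2 was at least 9.21-fold lower and the clock-linked repressor gene Bhlhe41 at least 6.37-fold lower.

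By list, 17 of 20 cytokines rose in KO cells and 1 fell, with Il1a at 3.70 ± 0.11 and Tnfsf9 at 2.49 ± 0.10. The list median was 2.31, 2.09 with 3 genes at their lower bound and 2.30 with the slide as a term. For LPS in KO that term sets the LPS arrays against KO PBS replicate 3 alone. Interferon-stimulated genes rose less: 27 of 33 were called higher and 0 lower, with a median of 0.62. With the slide as a term 22 were called higher, at a median of 0.57. Oasl1 rose by 2.04 ± 0.11, Isg15, a ubiquitin-like modifier, by 1.63 ± 0.11 and Isg20 by 1.25 ± 0.06. Feedback genes rose in 21 of 26 and fell in 2, including Tnfaip3 at 2.40 and Il10 at 2.64, at a median of 1.33 and 1.40 with the slide term. Of the signalling components 16 rose and 5 fell, at a median of 0.28 and 0.42 with the slide term.

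In KO cells too, falls outnumbered rises in several lists, of which 0 were called with an estimated correlation. Large peritoneal macrophage identity genes, those of the main resident population, fell in 14 of 26 and rose in 5, with Naip1 at -2.14 and Tgfb2 at -1.30. Phagocytosis and scavenger receptors fell in 13 of 27 genes and rose in 3; Trem2, a lipid-sensing receptor gene, fell by 1.01 and its adaptor gene Tyrobp by 0.97. Efflux and LXR targets fell in 11 of 18 genes and rose in 2, cholesterol biosynthesis fell in 12 of 21 and rose in 2, and NRF2 targets fell in 12 of 20 and rose in 3. Abcg1, which exports cholesterol, fell by 1.19 and Scd2 by 1.85. The unfolded protein list had 13 rises and 4 falls. B-cell markers fell in 11 of 13 genes and rose in 0, with Cd79b at -2.44.

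For LPS in KO cells, 8904 genes (67.0%) were called, 4657 higher and 4247 lower, and 1907 changed at least 2-fold, 942 higher and 965 lower. With quantile normalization 4154 were higher and 4764 lower, and with normexp 588 were at least 2-fold higher and 491 lower. The slide term left 7035, of which 6530 were shared with the fit without it. Adjusted over the list alone, 28 interferon-stimulated genes, 17 signalling components, 2 phagocytosis genes and 4 citric acid cycle genes rose. Falls numbered 10 for alternative activation and 0 for mast-cell markers, and the other counts were the same.

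The list test called 11 lists in KO cells, and 0 with an estimated correlation. Without KO PBS replicate 3, the PBS array of slide 2, it called 7. Interferon-stimulated genes gave an adjusted p of 5.4e-06, 4.9e-05 with the slide term, and adjusted p = 0.578 with an estimated correlation, the highest over 29 alternatives, whose lowest was 1.2e-10. Cytokines gave 1.4e-05 and adjusted p = 0.217 with an estimated correlation, and the feedback list 3.2e-06 and adjusted p = 0.173. Efflux genes gave 0.00342 and adjusted p = 0.173 with an estimated correlation, NRF2 targets 0.036 and adjusted p = 0.358, and B-cell markers 0.00021 and adjusted p = 0.383. The medians of these lists were -0.49, -0.38 and -0.86, and -0.53, -0.33 and -1.12 with the slide term.

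Weaker calls in KO cells were those for signalling components at 0.0404, with adjusted p = 0.71 under an estimated correlation, and unfolded protein genes at 0.0474, with adjusted p = 0.59 under it. Cholesterol biosynthesis gave 0.0418, adjusted p = 0.217 with an estimated correlation and 0.0795 with the slide term. Under 4 other scalings of the arrays, signalling components and cholesterol biosynthesis were each called under 1, with adjusted p up to 0.0804 and 0.078, and unfolded protein genes under 0, with adjusted p up to 0.0884. Identity genes gave 0.0404 and adjusted p = 0.675 with an estimated correlation, and phagocytosis genes 0.0404 and adjusted p = 0.23. Their medians were -0.30 and -0.26, or -0.36 and -0.23 with the slide term.

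The responses of both genotypes shared most genes. LPS raised 3559 genes in both WT and KO cells, where independent calls would give 1570.3, and lowered 3512 in both, where they would give 1315. Only 66 genes rose in WT and fell in KO cells, and 15 did the reverse. Across genes, which are not independent replicates, the WT and KO changes correlated at r = 0.88.

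**Figure D2:**
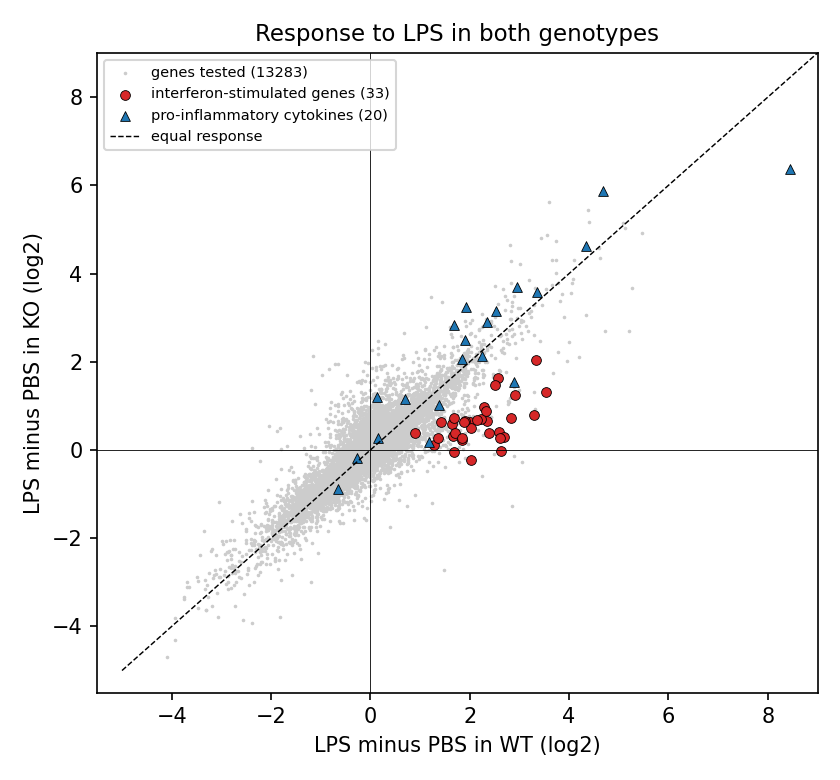
Log2 change by LPS in WT cells (x axis) against that in KO cells (y axis) for each of 13283 genes, with the 33 interferon-stimulated genes as red circles, the 20 pro-inflammatory cytokines as blue triangles and a dashed line where both changes are equal. Interferon-stimulated genes lie under the line, with medians of 2.15 in WT and 0.62 in KO cells, and cytokines near it, with medians of 1.92 and 2.31.

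What the loss of GPR15 changed in unstimulated cells was asked by comparing KO with WT in PBS. All 33 measured interferon-stimulated genes were higher in KO cells before any LPS was added, at a median of 0.74 and adjusted p = 0.244 with an estimated correlation. Cxcl10 was higher by 1.56 ± 0.13. The inflammatory gene S100a9, abundant in neutrophils, was higher by 2.64 ± 0.50. Chil3, a chitinase-like lectin gene of alternatively activated macrophages, was higher by 1.92 ± 0.19 and the neutrophil chemokine gene Cxcl1 by 2.03 ± 0.11. Slc15a2, which imports bacterial peptides, was higher by 2.19 ± 0.41.

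Other genes higher in KO cells in PBS were Cndp2, a dipeptidase gene, at 1.56 ± 0.07, Tppp3 at 1.65, the fatty acid carrier gene Fabp7 at 1.47 and the formyl peptide receptor gene Fpr-rs6 at 1.40, or 0.71 with the slide as a term. Lrmda was at least 23.9-fold higher. Among genes lower in KO cells, Cxcl5 was at -1.88 ± 0.36, the phosphatidylserine decarboxylase pseudogene Pisd-ps3 at -1.80 and Emid1 at -2.00. Csf3 was at -1.66 ± 0.42, with an adjusted p of 0.0223 and of 0.0522 with the slide term, and Aebp1 at -1.52, with 0.0344 and 0.0739. The collagen gene Col18a1 was at -1.38 and Tgfb3, a growth factor gene, at -1.35. Clec4g, a lectin gene, was at least 3.67-fold lower and Cyp1b1 at least 2.41-fold lower.

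Among antiviral genes in PBS, Xaf1 was higher in KO cells by 0.74 ± 0.06, Oasl2 by 0.79 ± 0.07, Ifih1 by 0.77 ± 0.08 and Oas3 by 0.77 ± 0.08. With the slide as a term the list median was 0.66 and 32 of 33 genes were called higher. Antimicrobial and effector enzymes were higher in 9 of 25 genes and lower in 0, with the scavenger receptor gene Marco at 0.64, the haptoglobin gene Hp at 0.61 and Acod1, which makes itaconate, at 0.46. Immediate early genes, the first to respond to stimulation, were lower in 7 of 22 and higher in 1, with Fosl1 at -0.80 and Nr4a1 at -0.52. Cytokines went both ways, 4 higher and 2 lower of 20: Tnf was at 0.74 ± 0.09 and Il18 at 0.66 ± 0.07, with Il6 among the lower ones. Chemokines did as well, with 5 higher and 5 lower of 23.

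Markers of other cells differed too. B-cell markers were lower in KO cells in 7 of 13 genes, with Cr2 at -1.02, and T-cell markers in 6 of 14, with Cd3d at -0.76; 0 were higher in either list. Neutrophil markers were higher in 2 of 8 genes, S100a9 and Camp, and mast-cell markers lower in 1 of 9, Mcpt4 at -0.47. Adjusted over the list alone, the counts included 10 higher and 1 lower for enzymes, 2 higher and 11 lower for immediate early genes, 8 lower for B-cell and 8 lower for T-cell markers.

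In PBS 1874 genes (14.1%) were called between KO and WT, 1070 higher and 804 lower, and 152 differed at least 2-fold, 92 higher and 60 lower. With normexp these were 32 and 24, and with genes above background on all arrays 38 and 34. With the slide as a term 2014 were called, 1483 of them shared. That term takes KO cells in PBS from the 2 KO arrays of slide 1 only. Its differences are therefore the same as those of slide 1 alone, with 2 KO arrays against 3 WT arrays, and are no separate check. Slide 1 alone called 1087, of which 926 were shared. Leaving out WT PBS replicate 1 gave 917, WT PBS replicate 2 gave 1043 and WT PBS replicate 3 gave 2579, of which 128 were at least 2-fold higher and 135 lower. Of the called genes 57.1% were higher, but 43.4% with arrays scaled to their median.

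Of the 7 lists called in PBS, 0 were called with an estimated correlation. Interferon-stimulated genes gave an adjusted p of 6.4e-28, 2.8e-22 with the slide term and adjusted p = 0.244 with an estimated correlation, the highest over 29 alternatives, whose lowest was 1.4e-42. Enzymes, at a median of 0.20, gave 0.00132 and adjusted p = 0.244 with an estimated correlation, and immediate early genes, at -0.27, gave 0.00616 and adjusted p = 0.456. Their slide-term medians were 0.22 and -0.26. B-cell markers, at a median of -0.34, gave 7.9e-06, and T-cell markers, at -0.31, gave 0.00049; both had adjusted p = 0.244 with an estimated correlation. With the slide term these medians were -0.33 and -0.32. Neutrophil markers, at 0.49, gave 0.0336, adjusted p = 0.244 with an estimated correlation and 0.124 with the slide term. Mast-cell markers, at -0.25, gave 0.0166 and adjusted p = 0.816 with an estimated correlation, at -0.42 with the slide term.

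KO and WT cells after LPS were compared to ask what the loss of GPR15 changed under stimulation. The interferon-stimulated genes, higher in KO cells before LPS, were lower in them after it, with adjusted p = 0.244 and 0.615 for the list with an estimated correlation. Siglec1, an interferon-inducible sialic acid receptor gene, was at -2.00 ± 0.14, and Apol9b at -2.27 ± 0.26. Nos2 was at -1.59 ± 0.38, and its slide-term value of -1.77 had an adjusted p of 0.181. Fcgr1, the high-affinity antibody receptor gene, was at -1.98 ± 0.35, with 0.114 as its adjusted p under the slide term. Slc15a2, S100a9 and Chil3, higher in KO cells in PBS, were higher after LPS too, by 2.44 ± 0.41, 2.33 ± 0.50 and 1.82 ± 0.19.

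Because KO LPS arrays shared no slide with WT LPS arrays, values are set beside those of a fit with the slide as a term, which rests on the KO PBS arrays of both slides. With that term Slc15a2 was at 2.76 with an adjusted p of 0.0691, S100a9 at 1.92 with 0.273 and Chil3 at 1.53 with 0.0325. Sdk2, an adhesion gene, was higher by 2.21 ± 0.20 and 1.32 with the term, and the peroxisomal gene Nudt7 by 1.67 ± 0.10 and 1.28. Others shrank: the cardiac actin gene Actc1 went from 2.40 to 0.07, Fpr-rs6 from 2.32 to 0.24, the prolactin-family gene Prl3b1 from 2.16 to 0.54, the pheromone receptor gene Vmn1r48 from 1.84 to 0.04 and the odorant receptor gene Olfr319 from 1.74 to 0.28. Lrmda was at least 16.1-fold higher, a bound without the term.

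Among genes lower in KO cells after LPS, Siglec1 was at -1.74 and Apol9b at -2.05 with the slide term, at adjusted p of 0.00382 and 0.0353. Pisd-ps3 was at -1.94 ± 0.08, and -1.59 with the term. Itpka, an inositol phosphate kinase gene, was at -1.76 ± 0.11, and -1.75 with it. The lipase gene Lipg was at -2.23 ± 0.33, with an adjusted p of 0.115 under the slide term, and Inhbb, an activin subunit gene, at -2.13 ± 0.53, with 0.319. Over the 132 genes at least 2-fold lower, the term raised the median SE from 0.18 to 0.33. Those 2 lost calls alone therefore do not show a smaller difference. Clec4g was at least 4.03-fold lower and the calcium channel gene Cacnb4 at least 3.08-fold lower, also without the term.

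By list, 32 of 33 interferon-stimulated genes were lower in KO cells after LPS and 0 higher, at a median of -0.86, and -0.89 with the slide term, where 27 were called lower. Oas3 was at -1.25 ± 0.08, Isg20 at -1.14 ± 0.06 and the virus-tethering gene Bst2 at -1.01 ± 0.07, and with the term they were at -1.20, -1.28 and -0.93. Cytokines were higher in 8 of 20 genes and lower in 2, with Il12b at 0.81 ± 0.16 and Il1a at 0.65 ± 0.11. With the term these genes were at 1.18 and 0.39, the latter at an adjusted p of 0.234. The list median was 0.30, and 0.35 with the slide term, where 4 were called higher and 0 lower. Antigen presentation genes were lower in 11 of 24 and higher in 2, with the immunoproteasome genes Psmb8 at -0.82 and Psmb9 at -0.76; under the term their adjusted p was 0.055 and 0.0935. The median of -0.20 became -0.04 with the slide term, where 1 was called higher and 0 lower. Ly6c2 and Ly6c1, monocyte surface genes, were at -0.88 ± 0.07 and -0.84 ± 0.07, and at -0.95 and -1.02 with the slide term. The desaturase genes Scd1 and Scd2 were at -1.02 and -1.05, and both at -1.08 with the term. Cholesterol biosynthesis had 7 genes higher, such as Mvk at 0.66 and at 0.62 with the term, and 1 lower; the term left 3 and 0. B-cell markers were lower in 7 of 13 genes, with Vpreb3 at -1.38 and at -1.49 with the term, and 0 were higher; adjusted over the list alone 11 were lower, and with the slide term 2 were called.

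After LPS 5242 genes (39.5%) were called between KO and WT, 2653 higher and 2589 lower, and 496 differed at least 2-fold, 364 higher and 132 lower. The slide term left 776, 345 higher and 431 lower; 638 were shared with the fit without it and 1 went the opposite way. At least 2-fold were 48 higher and 102 lower with the term, 73 and 61 with normexp, and 153 and 86 with genes above background on all arrays. With no filter on dim probes they were 477 and 422 of 22911 genes. Scaling arrays to their median moved the median of all genes from -0.01 to -0.12 and the share of called genes that were higher from 50.6% to 30.2%. The list test called 2 lists and, with an estimated correlation, 0. Interferon-stimulated genes gave an adjusted p of 6.6e-20, 1.7e-28 with the slide term and adjusted p = 0.615 with an estimated correlation, the highest over 28 alternatives, whose lowest was 1.7e-28. B-cell markers, at a median of -0.31, gave 0.00531, 0.0007 at -0.36 with the slide term and adjusted p = 0.615 with an estimated correlation.

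Slide and signal level moved together in this comparison. A gene could also pass the filter through the KO LPS arrays alone. Without the filter the median of KO minus WT after LPS was -0.13 over all genes. How much the filter added to the values below was not tested. Among the dimmest 1329 genes the median of KO minus WT was 0.33 after LPS and 0.11 in PBS, and KO PBS replicate 3 on slide 2 exceeded replicates 1 and 2 on slide 1 by a median of 0.18. Receptor families of the nose, chosen after the values were seen, showed it as well: 45 of 85 odorant receptor genes (Olfr) were higher in KO cells after LPS and 1 lower, but 1 was called higher with the slide term. Their median slide difference within KO PBS, which sets the slide term, was 0.75. Of 24 vomeronasal receptor genes (Vmn), 11 were higher, 2 lower and 0 called higher with the slide term.

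**Figure D3:**
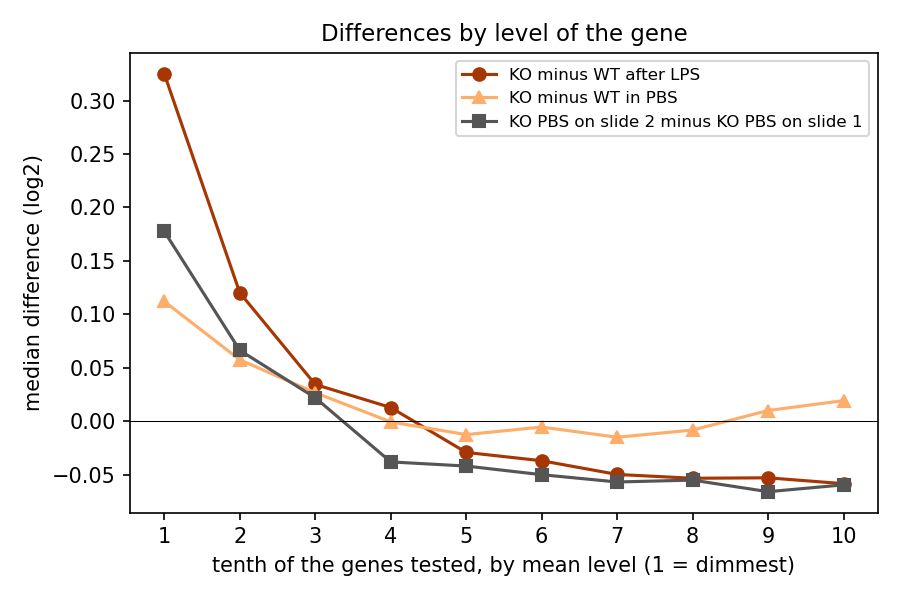
Median log2 difference (y axis) of KO minus WT after LPS, KO minus WT in PBS, and KO PBS replicate 3 on slide 2 minus replicates 1 and 2 on slide 1, over 10 groups of the 13283 genes ordered by mean level (x axis). In the dimmest group the medians were 0.33, 0.11 and 0.18, and in the brightest -0.06, 0.02 and -0.06.

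The differences between genotypes with and without LPS overlapped. Of the called genes 594 were higher in KO cells in both, against 213.7 for independent calls, and 514 lower in both, against 156.7. These counts have no slide term, which left 345 higher and 431 lower genes after LPS, fewer than either overlap. That term also raised the median SE over all genes from 0.088 to 0.136, so part of the loss may be lower precision. Another 152 genes were higher in PBS and lower after LPS, fewer than the 208.6 of independent calls, and 8 the reverse, against 160.6. Across genes, which are not independent replicates, both differences correlated at r = 0.55.

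Whether LPS acted differently in KO cells was tested as the interaction of genotype and LPS. The interferon-stimulated part of the LPS response was smaller in KO cells. Ifit3, which restrains viral RNA, had an interaction of -2.67 ± 0.21, Ifit3b -2.58 ± 0.22, Ifit1 -2.21 ± 0.24 and Ifit2 -2.19 ± 0.22. Rsad2, which makes an antiviral nucleotide, had -2.49 ± 0.23 and Cmpk2, its neighbour in nucleotide synthesis, -2.38 ± 0.18. Apol9b had the largest at -2.85 ± 0.36, and the GTPase gene Iigp1 had -2.24 ± 0.46.

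Ifi44, at -2.34 ± 0.25, and Ifit1bl1, at -2.45 ± 0.19, completed the 10 largest negative interactions. Cxcl10, whose rise was 4.72 in WT and 2.70 in KO cells, had -2.02 ± 0.18, and the chemokine gene Ccl5 -0.87 ± 0.20. Positive interactions were smaller: Nudt7 had 1.34 ± 0.14, the calcium channel gene Cacna1b 1.21 ± 0.28, Hepacam2 1.19 ± 0.19, the protease gene Prss28 1.14 ± 0.29 and the elastase gene Mmp12 0.97 ± 0.21. Cxcl3, a neutrophil chemokine gene, had 0.88 ± 0.14 and Naip1 had 0.82 ± 0.16. Tnfrsf19, Slc25a30 and Strbp had 0.97, 0.92 and 0.88.

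Since all KO LPS arrays lay on slide 2, the slide term bears on these interactions too. For the interaction the KO PBS level is then that of replicate 3 alone, which limits the slide term. With it Nudt7 was at 1.08, Hepacam2 at 1.00, Cxcl3 at 0.65 and Naip1 at 0.99, all still called. Cacna1b went to 0.64 with an adjusted p of 0.0993, Prss28 to 0.64 with 0.261 and Mmp12 to 0.75 with 0.166. Tnfrsf19, Slc25a30 and Strbp lost their call as well, at 0.183, 0.227 and 0.153. Among negative interactions Iigp1 lost its call at 0.146 and Ccl5 at 0.223. Ifit3 was at -2.94, Rsad2 at -2.53, Apol9b at -2.70 and Cxcl10 at -1.82, and the other negative ones named above stayed called. Where only an adjusted p is given, a lost call may reflect a smaller difference or a larger SE.

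All 33 interferon-stimulated genes were called with a negative interaction, at a median of -1.48, and -1.55 with the slide as a term, where 32 were called. Isg20 had -1.67 ± 0.09, Oas3 -2.02 ± 0.12 and Oasl2 -1.68 ± 0.10. Per array the mean of the list was 2.43 ± 0.02 (SD, n = 3) in WT PBS, 4.61 ± 0.15 in WT LPS, 3.16 ± 0.08 in KO PBS and 3.78 ± 0.07 in KO LPS. Each pair of these groups that differed in LPS or in genotype was fully parted, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Antigen presentation genes had 7 negative and 1 positive interactions among 24, with Tap1, a peptide transporter gene, at -0.73, Psmb8 at -0.93 and Psmb10 at -0.85. Cytokines had 2 positive interactions, among them Il1a at 0.75 ± 0.15 and at an adjusted p of 0.134 with the slide term, and 1 negative, Il18 at -0.98 ± 0.10. Adjusted over the list alone they had 6 and 3, and antigen presentation genes 8 negative ones.

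The interaction was called for 573 genes (4.31%), 123 positive and 450 negative, and 152 were at least 2-fold, 20 positive and 132 negative. Of the 450, 202 were higher in KO cells in PBS, 399 lower after LPS and 152 both, and these counts share arrays with the interaction by construction. With the slide as a term 393 were called, 67 positive and 326 negative, 332 of them shared. The count rested on single arrays: it was 2797 without KO PBS replicate 3, 960 without WT PBS replicate 3, 360 without WT PBS replicate 1, 361 without KO PBS replicate 1 and 365 without KO LPS replicate 1. At least 2-fold were 306 positive and 159 negative without KO PBS replicate 3, which turned the balance, and 65 and 143 without WT PBS replicate 3. Of the called genes 21.5% were positive, against 45.2% without KO PBS replicate 3 and 38.1% without WT PBS replicate 3. The share was 50.1% with array weights and 32.7% after another background correction with quantile normalization. The estimation of the array weights stopped before its tolerance and gave WT PBS replicate 1 a weight of 138.9, so their share is of little use.

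The list test called 2 lists for the interaction. For interferon-stimulated genes adjusted p was 8.4e-57, 3.8e-65 with the slide term and 0.0478 with an estimated correlation, within a range of 1.2e-74 to 0.0478 over 27 alternatives. Antigen presentation genes, at a median of -0.15, gave 0.00347, adjusted p = 0.698 with an estimated correlation and 0.114 at -0.06 with the slide term. Cytokines, at a median of 0.26, gave 0.384. Without WT PBS replicate 3 the test called 5 lists.

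**Figure D4:**
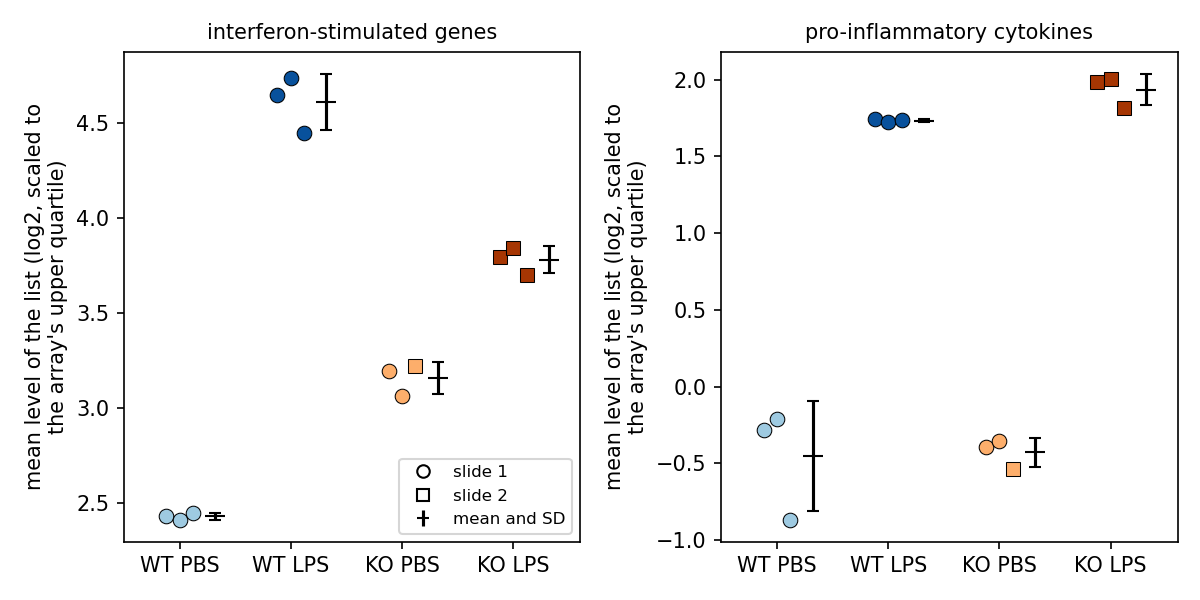
Mean log2 level per array, relative to the 75th percentile, of 33 interferon-stimulated genes and 20 pro-inflammatory cytokines by group, with circles for slide 1, squares for slide 2 and bars for the group mean and SD. The interferon-stimulated mean was 2.43 in WT PBS, 3.16 in KO PBS, 4.61 in WT LPS and 3.78 in KO LPS, whereas the cytokine mean after LPS was 1.73 in WT and 1.94 in KO cells.

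The size of the LPS response as a whole was compared over the genes that LPS changed in both genotypes on average, a set chosen on these arrays. Over 5232 raised genes the median change was 0.46 in WT and 0.46 in KO cells, with a median interaction of -0.030 and a camera p of 0.0141, or p = 0.269 with an estimated correlation. Quantile normalization turned that interaction to 0.0046 and array weights, whose estimation stopped before its tolerance, to 0.011. The camera p over 25 alternatives lay between 0.00022 and 0.627. Over 4680 lowered genes the medians were -0.54 and -0.53, with a median interaction of 0.0016, which camera did not call. The mean level of both sets after LPS differed between KO and WT by 0.00 and 0.02, with exact two-sided permutation p of 1 and 0.4, where 0.1 is the smallest possible.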

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

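All tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the arrays, which were planned; that for the median of the interferon-stimulated list was also chosen afterwards.

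The LPS response differed between WT and KO cells by a test of the difference itself for 573 genes. The interferon-stimulated list differed at a median interaction of -1.48, and antigen presentation and co-stimulation genes at -0.15. The latter call was lost with an estimated correlation, at adjusted p = 0.698, and with the slide term, at 0.114. Negative interactions were largest for Apol9b at -2.85, Ifit3 at -2.67, Ifit3b at -2.58, Rsad2 at -2.49 and Ifit1bl1 at -2.45, followed by Cmpk2 at -2.38, Ifi44 at -2.34, Iigp1 at -2.24, Ifit1 at -2.21 and Ifit2 at -2.19. Positive ones were largest for Nudt7 at 1.34, Cacna1b at 1.21, Hepacam2 at 1.19 and Prss28 at 1.14, followed by Mmp12 and Tnfrsf19 at 0.97 each, Slc25a30 at 0.92, Strbp and Cxcl3 at 0.88 each and Naip1 at 0.82. With 1 array left out at a time, 20 of 53 genes named for the interaction lost their call in at least 1 fit.

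Probes without a gene name also responded to LPS and stand outside the comparisons of the report. Of 9761 such probes, 4593 were called in WT cells, 2530 higher and 2063 lower, and 5514 in KO cells, 3348 higher and 2166 lower. Between KO and WT 791 were called in PBS and 3787 after LPS.

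The first pattern weighed is the smaller LPS response of interferon-stimulated genes in KO cells. A slide difference is argued against as its whole cause, since the median interaction was -1.55 with the slide as a term. That value takes KO PBS from replicate 3 alone, so this holds only as far as that array can show. Weaker LPS stimulation of the KO cultures that lowers all responses alike is argued against as well. Over 906 other genes raised at least 2-fold the median KO response was 97.5% of the WT response, against 29.0% for the list. With a single dose and time, weaker or later stimulation that touches only part of the response was not tested. A higher level before LPS that leaves less room is argued against because the list ended lower in KO cells, at a median of -0.86. Any other effect of that higher level on the later response was not tested and stays open. Sex and strain background were not tested apart from genotype and stay open, so the pattern is not assigned to the loss of GPR15.

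Other splits of the arrays were counted for this pattern. Of 100 splits drawn, 8, the real one included, called at least as many interaction genes as the real 573. The highest other count was 5699. All 8 kept the LPS arrays parted by genotype, and splits that mixed the genotypes among LPS arrays called at most 1 gene. The split with 5699 exchanged the genotypes of the LPS arrays only. Its interaction was therefore the difference between KO and WT over both stimulations. Such splits cannot tell whether chance gave the count of 573, so chance is not excluded for it. For the list median, 1 of 100 splits, the real one, lay as far from 0 as -1.48, and the farthest other was at 1.07 in size. That test was chosen after the list was seen to part by genotype in both stimulations. Whether replicates came from separate mice is not given, so these splits cannot exclude chance between mice.

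The second pattern is the 5242 genes called between KO and WT after LPS. Among the 364 at least 2-fold higher in KO cells, KO PBS replicate 3 on slide 2 exceeded replicates 1 and 2 on slide 1 by a median of 0.94, and 85.7% of these genes had a slide difference above 0. The slide term is set by that same difference, so their median of 1.28 becoming 0.34 with it is not separate support. Median SE was 0.29 without and 0.36 with the term, so most calls ended because the values shrank, and 40 remained called. A slide difference is a candidate explanation for many of the others, as far as KO PBS replicate 3 can show. Among the 132 at least 2-fold lower, the slide difference was 0.01. Their median was thus similar at -1.21 without and -1.28 with the slide term, and 72 were still called. This argues against the slide for these genes as a set, as far as KO PBS replicate 3 can show. With no filter on dim probes, 477 genes were at least 2-fold higher and 422 lower. The excess of higher genes therefore also depended on the filter. Over all 2589 lower genes the median went from -0.32 to -0.20 with the term, 389 stayed called and the slide difference was -0.11, so the slide stays open for the smaller differences.

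The third pattern is that 1065 autosomal genes, 8.27% of 12874, differed the same way between KO and WT with and without LPS. Sex remains open and was not tested apart from genotype: 6 of 6 KO arrays had all Y-linked genes above background, and 1 WT array had one. A segment next to Gpr15 carried over from another strain could not be settled: 3 of 15 neighbouring genes, Cldnd1, Dcbld2 and Tbc1d23, differed the same way in both, with a one-sided hypergeometric p of 0.122. Those 3 were named after their values were seen. The slide stays open as well: with the slide term 776 genes were called after LPS in all, fewer than 1065. That term also raised the median SE over all genes from 0.088 to 0.136, so lost calls alone do not show a slide difference. In PBS, where the term takes KO cells from the arrays of slide 1 only, 2014 genes were called with it. Of these, 1483 were shared with the fit without it.

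For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, reached the real count. After LPS the split of KO from WT called 5242 genes and the highest other 0. In PBS it called 1874 and the highest other 1. LPS against PBS called 8593 in WT and 8904 in KO, and the highest other 0 in either. Of the 10 splits of the WT arrays 4, the real one among them, part all pairs of equal replicate number; the others keep 1 such pair whole on each side.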

How the results depend on the processing

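Tests on slide 1 or slide 2 arrays alone, on WT arrays alone with the replicate block, on autosomal genes and with the slide block and genes above background on all arrays were chosen after the results were seen; the others were set beforehand, but normexp used the median signal for want of a mean signal. The direction of the interferon-stimulated list held in every comparison under the alternatives run, at medians of 1.95 to 2.30 for LPS in WT, 0.46 to 0.65 for LPS in KO, 0.64 to 0.78 and -0.97 to -0.72 for KO against WT in PBS and after LPS, and -1.55 to -1.38 for the interaction. Of all values of counts, lists and response size under alternatives, 438 were counted as unchanged. For counts this means within 1.5 times, and for other values the same side of the threshold. Their direction was kept too, except that values uncalled in both fits could change sign. A further 49 counts moved beyond 1.5 times, 11 values lost their call, 5 gained one and 4 reversed with a call on either side. Signal over background limits the rest: genes below it on all arrays, Gpr15 among them, give no fold, and none is given for Gpr15 under any alternative. The slide term for LPS in KO, for KO against WT after LPS and for the interaction rests on 1 KO PBS array of slide 2. Unless stated, the cause of a change was not tested.

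Estimated correlations called 0, 0, 0, 0 and 1 lists for LPS in WT, LPS in KO, KO against WT in PBS, the same after LPS, and the interaction, against 9, 11, 7, 2 and 2 with the preset one; fry called 26, 22, 11, 16 and 5. With estimated correlations the interferon-stimulated medians were the same at 2.15, 0.62, 0.74 and -0.86, with adjusted p of 0.227, 0.578, 0.244 and 0.615: by construction the same shift was set against a wider variance. No filter called 14 lists for LPS in WT, 11 for KO against WT in PBS, 6 after LPS and 4 for the interaction. Lists called for KO against WT after LPS numbered 4 with quantile normalization, 4 with every probe by itself and 4 with the slide block and all arrays above background, against 2. The interaction had 1 with array weights and 1 with the slide block.

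The response size of raised genes lost its call with an estimated correlation at the same -0.030, with median scaling at -0.082, normexp with the 75th percentile at -0.017, no filter at -0.031 and every probe by itself at -0.025. It reversed with quantile normalization to 0.0046, with normexp and quantiles to 0.0091 and with array weights to 0.011. For lowered genes, at 0.0016 and not called, genes of at least 2-fold gave 0.079 and the slide block 0.058, both called, and no filter gave -0.0015, also called. Uncalled values lay on both sides of 0, down to -0.051 with median scaling. Over all alternatives p ranged from 0.00022 to 0.627 for raised and from 0.00031 to 0.914 for lowered genes.

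Counts of called genes with every probe by itself, which tests more items, were 16329 and 17534 for LPS in WT and KO, 2905 and 10546 for KO against WT in PBS and after LPS, 866 for the interaction and 19823 for the average LPS effect. Array weights gave 8832, 9296 and 7932 for KO against WT in PBS, after LPS and the interaction; their estimation stopped before its tolerance and ran from 0.0958 for KO PBS replicate 3 to 138.9 for WT PBS replicate 1, and why the counts rose was not tested. Requiring 2-fold, which removes small changes, left 2071, 1907, 152, 496 and 152 for LPS in WT, LPS in KO, KO against WT in PBS and after LPS, and the interaction. An adjusted p below 0.01 left 710, 2867 and 290 for the last 3. For KO against WT in PBS only the 2 groups called 799 and slide 1 arrays alone 1087, both with fewer arrays. The slide block called 776 after LPS, and 784 with genes above background on all arrays. With the replicate number as a block counts were 8599, 8967, 1941, 5214 and 576.

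Leaving out 1 array at a time, the interaction count ran from 360 without WT PBS replicate 1 to 2797 without KO PBS replicate 3, with 361 without KO PBS replicate 1, 365 without KO LPS replicate 1 and 960 without WT PBS replicate 3. The count for KO against WT in PBS ran from 917 without WT PBS replicate 1 to 2579 without WT PBS replicate 3. Lists called ran from 7 without KO PBS replicate 3 to 13 without WT PBS replicate 3 for LPS in KO, and from 2 without WT PBS replicate 1 to 5 without WT PBS replicate 3 for the interaction. The response size ran from -0.051 without WT PBS replicate 2 to -0.0051 without KO PBS replicate 3 for raised and from -0.041 without KO PBS replicate 3 to 0.024 without KO PBS replicate 2 for lowered genes. Of 12 such fits 2 ended the call of raised genes, those without WT PBS replicate 3 and KO PBS replicate 3, and 3 made one for lowered genes.

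Among named genes, Mgl2 reversed with the mean of probes to -0.13 for LPS in WT and 0.029 for KO against WT in PBS, and Eif2s3y with array weights to -0.12 for LPS in WT, a sign without meaning since it was above background on 1 of 6 WT arrays. Prf1 reversed with the slide block to -0.0047 for LPS in KO, and with the slide block to -0.23 for KO against WT after LPS, where Krt8 reversed to -0.089. With the slide block 82 of 136 named genes lost their call for KO against WT after LPS, 8 of 106 in PBS, 19 of 53 for the interaction and 8 of 149 for LPS in KO.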

Other observations

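The lists and their tests here were set beforehand; medians with bounds and group means of markers were added after the results were seen. LPS shifted metabolic genes in both directions. Glycolysis had 7 of 22 genes higher and 11 lower in WT and 7 and 10 in KO cells, with the regulator gene Pfkfb3 at 2.74 and 2.43 and Tpi1 at -0.56 and -0.64. The citric acid cycle and respiratory chain held 9 rises and 9 falls among 29 genes in WT and 5 and 10 in KO cells, with Idh2 at -1.25 and -0.82. Cell cycle genes fell in 18 of 30 and rose in 6 in WT cells, and fell in 20 and rose in 7 in KO cells; the cyclin gene Ccna2 was at -1.75 and -1.60, whereas Ccnd2 was at 3.02 and 2.96. Their median was -0.57 in WT, -0.52 with 2 genes at their lower bound, and -0.51 in KO cells. Immediate early genes rose in 13 of 22 and fell in 4 in WT, and rose in 11 and fell in 4 in KO cells, with Myc at 2.27 and 2.50. Coagulation and fibrinolysis genes held 7 rises and 5 falls among 17 in WT and 7 and 6 in KO cells; Plat, the tissue plasminogen activator gene, rose at least 6.92-fold and 8.12-fold. None of these lists was called by the preset-correlation test for LPS in either genotype.

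Effector and surface lists were mixed. Chemokines rose in 13 of 23 genes and fell in 6 in WT and in 13 and 5 in KO cells, with Ccl3 at 1.97 and 2.29. Antimicrobial enzymes rose in 14 of 25 and fell in 7 in WT, and rose in 12 and fell in 8 in KO cells, with Arg2 at 1.74 and 1.40. Antigen presentation genes rose in 14 of 24 and fell in 8 in WT cells but rose in 7 and fell in 11 in KO cells, with Cd40 at 2.62 and 1.78. Alternative activation genes rose in 5 of 19 and fell in 9 in WT, with the same counts in KO cells. Small peritoneal macrophage and monocyte genes rose in 6 of 21 and fell in 8 in WT, and rose in 3 and fell in 12 in KO cells, with the integrin gene Itgax at -2.94 and -2.84. In WT cells identity genes rose in 4 and fell in 12 of 26, and phagocytosis genes rose in 7 and fell in 14 of 27. Genes next to Gpr15 rose in 7 of 15 and fell in 5 in WT, and rose in 8 and fell in 6 in KO cells. In the sex-linked list of 9 genes the X-linked genes Eif2s3x, Ddx3x and Kdm5c rose after LPS in WT cells, 3 genes rose in KO cells and 0 fell in either; Y-linked genes in WT cells were left out of this count, being above background on at most 1 of 6 WT arrays.

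T-cell markers fell in 8 of 14 and rose in 1 in WT and fell in 5 and rose in 2 in KO cells, with Cd2 at -1.86 and -1.95. NK-cell markers rose in 2 of 5 in WT and 3 in KO cells and fell in 1 in either, with the granzyme gene Gzma at 2.27 and 1.80. Mast-cell markers rose in 3 of 9 and fell in 2 in WT and rose in 4 and fell in 1 in KO cells, with Hdc, the histamine-forming enzyme gene, at 1.54 and 1.44. Neutrophil markers rose in 3 of 8 and fell in 2 in WT, and rose in 2 and fell in 2 in KO cells. Eosinophil markers rose in 1 of 5 in either genotype and fell in 1 in WT and 2 in KO cells. Dendritic-cell markers rose in 3 of 7 and fell in 1 in WT and rose in 4 and fell in 2 in KO cells, with Flt3 at 1.27 and 1.60. Of the mesothelial, fibroblast, endothelial and erythroid lists 2, 2, 3 and 5 genes were measured, of which 2, 1, 2 and 0 were called in WT cells. Macrophage markers fell in 7 of 14 and rose in 3 in WT and fell in 10 and rose in 2 in KO cells, with the growth factor receptor gene Csf1r at -1.28 and -1.13.

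Mean levels per group, with n = 3, are read across groups within a list only, since levels of different probes are not comparable. B-cell markers had 2.47 ± 0.17 (SD) in WT PBS, 1.30 ± 0.12 in WT LPS, 2.07 ± 0.03 in KO PBS and 0.91 ± 0.06 in KO LPS. Macrophage markers had 4.52, 4.41, 4.56 and 4.31 in the same order. The median, mean and test of a list differed in sign for 1 list for LPS in WT, 3 for LPS in KO, 8 and 7 for KO against WT in PBS and after LPS and 3 for the interaction. Among them were the genes next to Gpr15, with a median of 0.30 and a mean of -0.09 for LPS in KO, and camera called 0 of those lists. Fry called the genes next to Gpr15 for LPS in WT at an adjusted p of 0.00642, glycolysis for LPS in KO at 0.0372, and small peritoneal macrophage genes for KO against WT at 0.04 in PBS and 0.02 after LPS.

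Between the genotypes further lists held smaller numbers of calls. After LPS the unfolded protein list had 9 of 22 genes lower in KO cells and 0 higher, small peritoneal macrophage genes 5 higher and 6 lower, efflux and LXR targets 3 and 7, and signalling components 4 and 8. Dendritic-cell markers were lower in 4 of 7, with Ccr9 at -1.07, and in 2 in PBS. The counts after LPS have no slide term, with which 776 of all genes were called after LPS in place of 5242. Phagocytosis genes were higher in 5 and lower in 0 of 27 in PBS, and identity genes higher in 6 and lower in 0 of 26, with Adgre1, the F4/80 gene, at 0.40 and Timd4 at 0.65.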
